A study of Mus musculus with 6 samples.

How the data were processed

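Total RNA from mouse testes was measured on 6 Affymetrix mouse exon arrays, 3 from wild-type (WT) and 3 from Ttll5 knockout (KO) animals, with biotin-labelled target made from Trizol extracts per the labels. The labels describe 3 biological replicates per group, age- and sex-matched littermates, and a mixed genetic background of the strains C57BL/6, 129/SvEv and FVB/N. Each array is taken as 1 animal or pool of its group, and no label ties an array to a litter or a hybridization day. The p-values measure the spread between these 6 samples.

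The authors deposited a single table of log2 probe set values for all 6 arrays. Per the submitters' processing notes, RMA and Partek 6.5 were used; the notes give no role or order for them, and the background correction, the probe set subset and the annotation are not given in the sources used here. RMA is a method that corrects background, makes array distributions alike by quantile normalization and summarises probes on a log2 scale. Values of the deposited table ran on a log2 scale with array medians of 6.72 to 6.77, so they were used as deposited, with no further normalization or pseudocount. Because RMA makes arrays alike, a change shared by most genes would not be visible in these values.

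The table holds 188590 probe sets, each covering part of an exon or a region of a transcript. The platform annotation gave 1 gene symbol for 179163 of them (95%), several symbols for 1322 and none for 8105. Only probe sets with 1 symbol entered gene values, and probe sets with several symbols named no gene. A gene's value was the mean of the log2 values of its probe sets, with no filter on dim probe sets, which gave 15792 genes with a median of 9 probe sets each. Of these symbols, 13716 were current in the RefSeq table of assembly GRCm38.p6, 2039 matched through an older name and 37 did not match. That table was used only for current names, chromosomes, and which genes neighbour each other, since the build behind the array annotation is not given in the sources used here; no coordinates are printed, and the order of the probe sets within a gene is unknown.

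KO was compared with WT in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, two-sided, without covariates, on genes and separately on probe sets. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. An exact permutation test of 3 arrays against 3 cannot give a p under 0.1, so all tests of single genes rest on limma's pooled spread. Differential exon use was tested with limma's diffSplice and Simes p-values in the 14152 genes with 3 or more probe sets. Gene lists were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry; 26 lists had the required 4 or more measured members. A further test asked whether called genes were more frequent within 10 Mb of Ttll5, with Fisher's exact test, because a knockout allele can carry linked sequence of the strain in which it was made.

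The comparisons, gene lists, alternatives and naming rule were fixed before the data were examined. The rule named Ttll5 first, then up to 12 genes per direction past the threshold with non-overlapping groups, by size of difference. A direction with too few such genes was filled up to 8 with the smallest unadjusted p-values among genes with non-overlapping groups, given as not past the threshold. It passed over clone-type symbols, up to 4 members were named per list, 6 genes for exon use, and every called gene near Ttll5. Genes named outside that rule are said to be.

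The scripts were tested on simulated arrays, with noise drawn independently for each gene or probe set at limma's moderated spread of these arrays. Correlation between genes and structure among the arrays were not simulated, so the rates on the real arrays can differ. In the gene test of KO against WT over 15792 genes, 73.1% of genes shifted by 0.5 on the log2 scale, 98.5% of those shifted by 1 and 100% of those shifted by 2 were recovered, with 9 false calls and 0 calls when nothing was changed. The planned exon use test over 14152 genes recovered 87% of genes with 1 probe set moved by 1 and 100% of those moved by 2, with 375 false calls. The planned test assumes that all probe sets of a gene share a variance, and it is not calibrated where they do not. A version in which each probe set kept its own variance, added after the data were seen, recovered 35% and 97% with 7 false calls. Both are given.

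Alternatives covered the gene summary, filters on dim probe sets and genes below the 40th percentile, normalization, moderation, array weights, a replicate block, leaving out each array, windows of 5 and 20 Mb, and the set test. Added after the data were seen were fits without the genes of chromosomes 12 and 9, a term for 3 arrays whose values had a higher lower quartile, the second exon use test and 2 further gene lists. Those 3 arrays (WT 1, KO 2, KO 3) are a cut by rank. The next array, WT 3 (4.64), lies nearer to them than to KO 1 (4.60) and WT 2 (4.59). Compared as deposited and without tolerance, at most 17 of the 188590 values were equal between any pair of arrays, and the differences of every pair had an SD of 0.35 to 0.45 (log2), so no array was found to repeat another. Array correlations ran from 0.985 to 0.991. The number of arrays limits the precision. Of the 28 lists written, the erythroid and the Y-linked list had too few measured genes and were not tested. Figures were drawn with Python 3.11.15.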

Results

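Gene expression was measured in testes of male mice lacking Ttll5 (tubulin tyrosine ligase-like 5, also named STAMP) and of WT littermates, with 3 arrays per group. Ttll5 belongs to a family of enzymes that add amino acids, mostly glutamate, to tubulin, and has also been described as a partner of steroid receptor coactivators. According to the series title, loss of the gene leads to malformed sperm and infertility, and the arrays address which testis transcripts differ in its absence. The 6 arrays had median probe set levels of 6.72 to 6.77 (log2) over 188590 probe sets. All differences below are KO minus WT on the log2 scale.

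Ttll5 transcript fell in every KO testis. Its level was 11.15 ± 0.015 in WT and 9.53 ± 0.043 in KO (log2, mean ± SD, n = 3 arrays each), a difference of -1.62 (SE 0.066, limma adjusted p = 4.3e-05), or 3.07-fold lower. All 33 probe sets of Ttll5, which lies on chromosome 12, were lower in every KO array than in every WT array, and 19 passed the probe set threshold. A pair of them lost nearly all signal. The first fell by 8.20, from 11.45 to 3.25, and the second fell by 6.27, from 10.46 to 4.19. The first KO level lies near the 5th percentile of the arrays and the other below their lower quartiles. Background alone would therefore make the WT share left, 0.339% and 1.30%, an upper bound. The other 31 differed by -0.80 to -1.78 with a median of -1.24, so that a median of 42.3% of the WT signal (29.2% to 57.3%) was measured in KO, although 1 of the 31 had a KO mean of 4.27, just above that of the second of the pair. Without the pair, the gene-level difference was -1.26 (SE 0.067, adjusted p = 0.00022). Which part of the gene the pair covers, and which part was deleted, is not given in the sources used here.

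**Figure D1:**
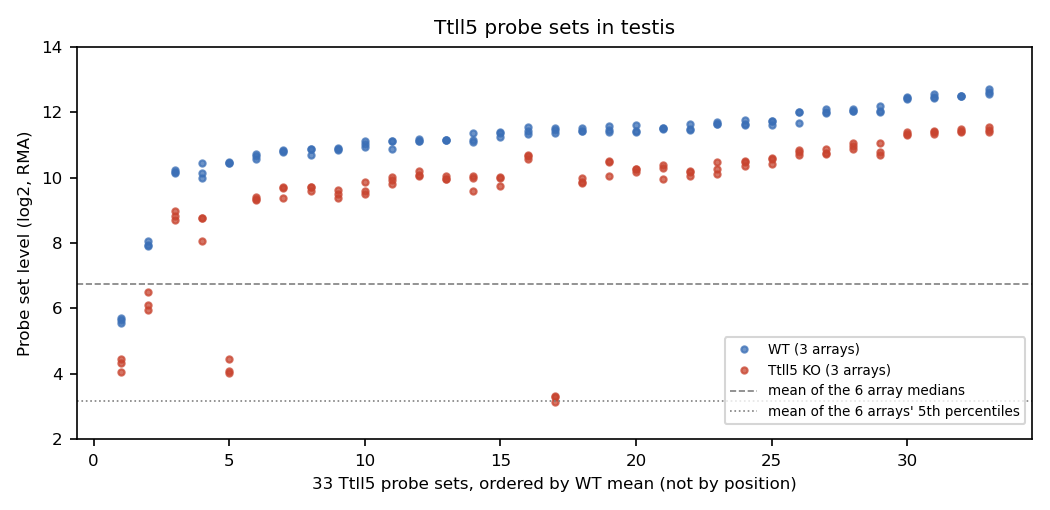
Levels (log2, y axis) of the 33 Ttll5 probe sets, ordered by their WT mean (x axis, not by position), in the 3 WT and 3 KO arrays, 1 point per array, with the mean of the 6 array medians as a dashed line and of their 5th percentiles as a dotted line. All 33 were lower in KO, and 2 fell from 11.45 to 3.25 and from 10.46 to 4.19.

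The other genes past the threshold were few, and in the main test all lay on chromosomes 12 and 9. Of 15792 genes, 11 passed (limma, adjusted p under 0.05), 7 higher and 4 lower in KO with Ttll5 among the latter, and in each of them all 3 KO arrays lay on one side of all 3 WT arrays. The largest rise was that of Serpina3g, a serine protease inhibitor of chromosome 12, from 3.85 ± 0.10 to 8.96 ± 0.71 (mean ± SD, n = 3 each), a difference of 5.11 (SE 0.30, adjusted p = 0.00035). The WT level lies below the lower quartile of every array (4.59 to 4.67) and is not shown to be above background. Background alone would make the 34.6-fold ratio a lower bound, but base differences under the probes are not excluded and would not. The same holds for the sizes given for Tshr and Tdgf1. Tshr, the thyrotropin receptor, rose by 1.94 (SE 0.081, adjusted p = 4.3e-05), from a level of 3.79 to 5.73. With dim probe sets left out the 1 of its 15 that remained rose by 3.81 (limma adjusted p = 0.0043). That probe set had a WT level of 4.25 and a KO level of 8.06. The filter used the mean over all 6 arrays, so its KO level kept it, and the larger rise is no separate support. Prps1l1, a testis-specific phosphoribosyl pyrophosphate synthetase, rose by 1.60 (SE 0.067, adjusted p = 4.3e-05). 2810002N01Rik, now Coa8, a cytochrome c oxidase assembly factor, rose by 1.87 (SE 0.084, adjusted p = 5.6e-05) (named by its current symbol, as the naming rule passes over clone-type symbols). Ston2, an adaptor of endocytosis, rose by 0.92 (SE 0.093, adjusted p = 0.013). These 5 and Ttll5 lie on chromosome 12.

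On chromosome 9, Scn10a, a voltage-gated sodium channel, rose by 0.89 (SE 0.071, adjusted p = 0.0028), and Tdgf1, a co-receptor of Nodal, rose by 0.91 (SE 0.091, adjusted p = 0.012). The 1 of its 4 probe sets kept by the filter on dim values rose by 1.76 (limma adjusted p = 0.0065), from 5.20 to 6.96. Since the filter counts the KO arrays, it favours probe sets that are high in KO, and this is no separate support. Lower on the same chromosome were Nme6, of the nucleoside diphosphate kinase family, with -1.07 (SE 0.075, adjusted p = 0.0012), Abhd14a, of the alpha/beta hydrolase fold family, with -0.99 (SE 0.086, adjusted p = 0.0048), and Pik3r4, a regulatory subunit of class III phosphoinositide 3-kinase, with -0.65 (SE 0.074, adjusted p = 0.030). Scn10a, Tdgf1, Tshr and Serpina3g had WT levels of 5.08, 4.38, 3.79 and 3.85, below the array medians, whereas Nme6 and Abhd14a had 9.77 and 9.26.

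The naming rule filled each direction up to 8 genes, with 1 higher and 5 lower genes not past the threshold. These were Rhbg on chromosome 3, an ammonium transporter, with a difference of 0.69 (adjusted p = 0.058), and 5 genes with lower values on chromosomes 12 and 9. The rule left out 5 genes whose p-values lay between theirs, all with higher values, 4 on chromosome 12 and 1 on the X chromosome. Among the lower genes were Arg2, mitochondrial arginase, with -0.95 (adjusted p = 0.069), and Dio2, the deiodinase that activates thyroid hormone, with -0.62 (adjusted p = 0.090). Tmem115 (-0.58, adjusted p = 0.061), Hemk1 (-0.58, adjusted p = 0.069) and Iqcf3 (-0.50, adjusted p = 0.14) lie on chromosome 9. With dim probe sets left out Rhbg (0.91, adjusted p = 0.021) and Dio2 (-0.75, adjusted p = 0.036) passed, and Hemk1 differed by -0.28 (adjusted p = 0.59). With dim genes left out Hemk1 passed (limma adjusted p = 0.044). Of 16 alternatives, Rhbg passed in 4, Tmem115, Arg2 and Hemk1 in 2 each, and Dio2 and Iqcf3 in 1 each. Over all genes, 955 had an unadjusted p under 0.05, 411 higher and 544 lower, where chance gives 790. The groups did not overlap in 11.2% of genes, where chance gives 10%. With the genes of chromosomes 12 and 9 left out, limma called 0 genes, while 820 of 14369 had an unadjusted p under 0.05. All 11 calls of the main test lay on those chromosomes, so the 0 was nearly fixed in advance and is no separate support.

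Pik3r4 lost its call without any 1 of the 6 arrays (adjusted p = 0.070 to 0.17), Tdgf1 without WT 2, WT 3, KO 1 or KO 2 (up to 0.080), and Ston2 without WT 1, WT 3 or KO 3 (up to 0.080). With the replicate block 8 of the 11 calls were kept, and Pik3r4 (limma adjusted p = 0.14) and Ston2 (0.11) were among those lost. With the median of a gene's probe sets in place of the mean, 5 genes were called, and Prps1l1 differed by 0.18 (adjusted p = 0.94), Nme6 by -0.55 (0.63), Pik3r4 by -0.38 (0.81), Abhd14a by -0.72 (0.31), Tdgf1 by 0.65 (0.56) and Scn10a by 0.97 (0.089). Ston2 kept its call at 1.42 (0.0041), and Hemk1 and Iqcf3, not called in either, stood at -0.26 and -0.18. With no moderation of variances 2 were called. Genes of other chromosomes were called in several settings, 3 of 12 without WT 1, WT 2 or KO 1, 2 of 11 without KO 3, 2 of 20 with trended and robust moderation and 2 of 14 with dim genes left out.

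**Figure D2:**
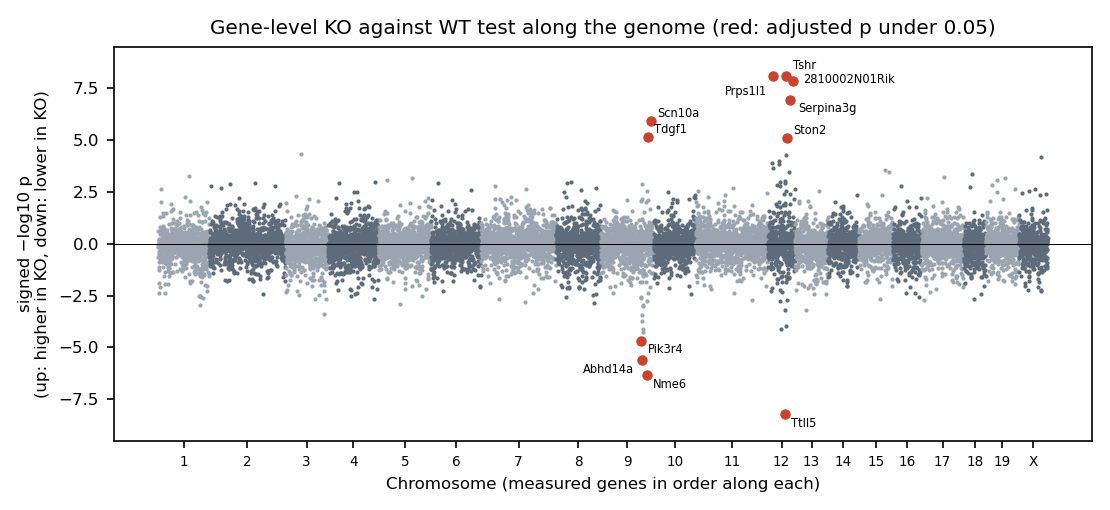
Signed -log10 p of the gene-level test (y axis, up for higher in KO) for all genes placed on chromosomes 1 to 19 and X, in gene order along each chromosome (x axis). Red points are the 11 genes past the threshold, all on chromosomes 12 and 9.

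**Figure D3:**
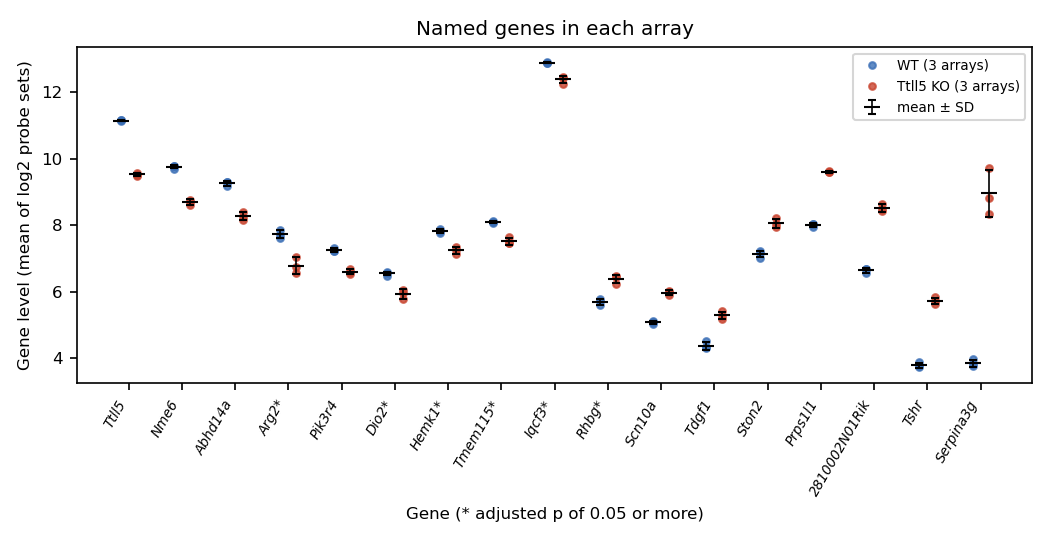
Gene level (log2, y axis) of Ttll5 and the other named genes (x axis) in each of 3 WT and 3 KO arrays, with mean and SD. The groups do not overlap in any of them, which the naming rule required of all but Ttll5, and an asterisk marks genes that did not pass the threshold.

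Single probe sets gave the same chromosomes. Among 188590 probe sets, 72 passed the threshold (limma), 38 higher and 34 lower in KO. Besides the 19 of Ttll5, 35 belonged to 16 other genes of chromosome 12 and all were higher, 16 belonged to 12 genes of chromosome 9 with 13 lower and 3 higher, 2 had no gene symbol (-3.33 and -3.43), and 0 belonged to another chromosome. Without adjustment 10109 probe sets had p under 0.05. The 4 called probe sets of Serpina3g rose by 4.27 to 6.11, and 9 of the 15 probe sets of Tshr passed. For the 3 of Serpina3g whose WT levels lie below the lower quartile of every array, background alone would make the rises lower bounds. In Prps1l1 3 of 5 probe sets passed, in Coa8 2 of 4 and in Ston2 4 of 9, while in many other genes only 1 passed. The examples that follow, where a smaller part of the probe sets passed, were chosen after their values were seen. In Gtf2a1, a subunit of the general transcription factor TFIIA, 1 of 6 probe sets rose by 5.15 (adjusted p = 0.0024) while the others had a median of -0.09. In Nrxn3, the synaptic adhesion gene neurexin 3, 2 of 24 probe sets passed and rose by 2.82 and 2.83, while those not past the threshold had a median of -0.05. Among the latter 1 rose by 3.50, from a WT level of 3.14, below the lower quartile of every array, to 6.64. In all, 4 of the 24 moved the same way at an unadjusted limma p under 0.05. For Fos, on chromosome 12, 1 of 6 probe sets rose by 1.51 (adjusted p = 0.026), and the others, not past the threshold, had a median difference of 1.00. The count was 13 to 37 with 1 array left out (13 without KO 2, 14 without WT 2 or WT 3, 28 without KO 1, 30 without KO 3, 37 without WT 1). It was 3 without moderation, 7 with the replicate block, 125 with trended and robust moderation, and 25 with a term for the 3 arrays (WT 1, KO 2, KO 3) that had a higher lower quartile of values.

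Probe sets that departed from the rest of their gene were compared next, as a measure of exon use. In Six6os1, 1 of 17 probe sets of a chromosome 12 gene now named 4930447C04Rik was higher in KO by 4.41, against a median of 0.07 for the rest. In Actr10, a dynactin subunit, 1 of 13 was higher by 2.39 against -0.18. On chromosome 9, Atp2c1, a Golgi calcium pump, had its leading probe set at -2.86 against a median of -0.06 for the rest of its 32. A second of Atp2c1 stood at -2.48, and 7 of the 32 moved the same way at an unadjusted limma p under 0.05. Iqcf3 had 1 at -3.52 against -0.06. Hemk1 had its leading probe set at -3.71 against -0.14, with a second at -1.47. The WT level of the Six6os1 probe set (4.47) lies below the lower quartile of every array. The same holds for the KO levels of the leading Hemk1 probe set (3.70) and the second of Atp2c1 (4.25). Background alone would make their differences lower bounds in size, but a base difference under a probe set is not excluded and would not. In Ttll5 the leading probe set stood at -8.20, a size that background limits in the same way, against -1.24. All 6 passed both exon use tests, with adjusted Simes p-values of 2.4e-05 to 0.027 when each probe set kept its own variance.

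The planned diffSplice test called 294 of 14152 genes, 44 on chromosome 12 (9.87% of its genes, Fisher's exact odds ratio 5.90, adjusted p = 8.6e-17), 44 on chromosome 9 (5.42%, odds ratio 3.00, adjusted p = 4.5e-08) and 206 elsewhere. Of the other chromosomes, chromosome 1 held more called genes than the rest (30, 3.57%, odds ratio 1.83, adjusted p = 0.026), and chromosomes 11 (1.02%, odds ratio 0.463, adjusted p = 0.028) and 7 (1.01%, odds ratio 0.464, adjusted p = 0.032) held fewer. Each was compared with all the rest, so chromosomes 12 and 9 raised the reference share for chromosomes 1, 11 and 7. Over the chromosomes other than 12 and 9 the share was 1.59%, and no test against that share was run. Fisher's exact test also treats genes as independent, although neighbouring genes can share linked sequence. On simulated arrays that test made 375 false calls, and with KO and WT arrays mixed in other splits of these arrays it called 86 to 1059 genes, so the 294 are not a count of changed genes. The count was 190 without WT 3, 179 without dim probe sets, 92 by a gene-level F-test and 158 without chromosomes 12 and 9. With a variance for each probe set, 12 genes were called, 8 of them on chromosome 12 besides Ttll5, 3 on chromosome 9 and 0 elsewhere, and all 12 were among the 294. That count was 5 to 9 with 1 array left out (8 without WT 1, 5 without WT 2, 5 without WT 3, 8 without KO 1, 5 without KO 2, 9 without KO 3), and 2, 2 and 1 of those without WT 1, KO 1 and KO 3 lay on other chromosomes. It was 5 with the term for WT 1, KO 2 and KO 3, and 0 of these lay on other chromosomes.

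Among the genes neighbouring Ttll5 on chromosome 12 of GRCm38.p6, Tshr and Ston2 lay within 10 Mb and were called. They made up 2 of 120 genes (1.67%), against 8 of 15634 elsewhere (0.0512%; two-sided Fisher's exact test, p = 0.0025, Ttll5 left out). Within 20 Mb, Serpina3g joined them (3 of 238, exact p = 0.00038), and within 5 Mb 0 of 79 were called by limma (p = 1), although 21.5% of those had an unadjusted p under 0.05. Fisher's exact test treats genes as independent, although neighbouring genes can share linked sequence, so its p-values can overstate the evidence. The 120 neighbours did not shift as a group (camera p = 0.15, and p = 0.16 with an estimated correlation), and 21.7% of them had an unadjusted p under 0.05. With 1 called neighbour left, Fisher's exact test no longer passed without WT 1 (p = 0.081), WT 3 (p = 0.052) or KO 3 (p = 0.074), and with no moderation 0 were called (p = 1).

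Gene lists fixed before the data were examined gave 7 of 26 past the threshold with camera's preset correlation, and 0 with an estimated correlation or with fry. No member of any list passed the test over all genes, so members below are given as values. Immediate early genes, the transcription factors and signalling genes switched on within minutes of a stimulus, were the list with the largest difference. Of 25 measured, 24 had higher values in KO, with a median difference of 0.37, and 15 passed, all higher, when adjusted over the list alone (0 over all genes). The list passed camera (adjusted p = 3.5e-21; adjusted p = 0.44 with an estimated correlation). Btg2 differed by 1.02 (SE 0.18), Ier3 by 0.78 (SE 0.14), the nuclear receptor Nr4a1 by 0.62 (SE 0.11) and the AP-1 subunit Fosl2 by 0.48 (SE 0.093). Fos and Egr1, named after their values were seen, differed by 0.94 (SE 0.19) and 0.77 (SE 0.17). In all of these the 3 KO arrays lay above the 3 WT arrays. Fos lies on chromosome 12, so linked sequence stays open for it. Without the genes of chromosomes 12 and 9, a fit added after the data were seen, the list differed by 0.41 (camera with the preset correlation, adjusted p = 1.1e-20). The mean level of the list was 6.06, 6.12 and 5.94 in the WT arrays and 6.66, 6.40 and 6.34 in the KO arrays. Within WT 1, KO 2 and KO 3 the list differed by 0.31, and within the other 3 arrays by 0.63.

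Leydig cell genes, markers of the cells that make testicular androgen, passed camera with the preset correlation only. Of 25 measured, 18 had higher and 7 lower values in KO, and 6 passed, all higher, when adjusted over the list alone (0 over all genes; camera adjusted p = 1.3e-06; adjusted p = 0.53 with an estimated correlation). Star, which carries cholesterol into mitochondria, differed by 0.55 (SE 0.13), Cyp17a1, an enzyme of androgen synthesis, by 0.39 (SE 0.090), and Aldh1a1, a retinaldehyde dehydrogenase, by 0.33 (SE 0.091). Nr4a1, at 0.62, is also a member of the immediate early list. The list stood at 7.60, 7.77 and 7.92 in WT and 7.97, 7.97 and 8.04 in KO, and differed by 0.41 within WT 1, KO 2 and KO 3 and by 0.13 within the other 3 arrays.

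Macrophage and leukocyte markers had higher values in 21 of 27 members with a median of 0.11, and only Cd14, a receptor for bacterial lipopolysaccharide (0.47, SE 0.082), passed when adjusted over the list alone (camera adjusted p = 0.00016; adjusted p = 0.53 with an estimated correlation). C1qa and C1qc, complement components, differed by 0.19 and 0.24. Glucocorticoid-responsive genes had higher values in 16 of 22, with Errfi1, an inhibitor of the EGF receptor (0.43, SE 0.086), alone passing when adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.57 with an estimated correlation). Mt1, a metallothionein, stood at 0.34, and Dusp1 (0.31) is also an immediate early gene. Fkbp5 and Sgk1, named after their values were seen, stood at -0.05 and 0.06. Peritubular myoid markers had higher values in 13 of 16, among them Lmod1 (0.20) and Smtn (0.16), and 0 passed when adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.74 with an estimated correlation).

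The spermatid lists passed camera with the preset correlation only, with small differences. Elongating spermatid markers, the genes of chromatin compaction and the sperm tail, had lower values in 29 of 36 with a median of -0.07, among them Spata19 (-0.26, SE 0.076), the transition protein Tnp1 (-0.19, SE 0.079) and Odf4 of the outer dense fibers (-0.18, SE 0.068). Round spermatid markers had lower values in 22 of 27 with a median of -0.08, among them Izumo1 (-0.23, SE 0.084), the sperm protein of egg fusion. In both lists 0 members passed when adjusted over the list alone. Camera gave adjusted p-values of 0.0012 and 0.0063, each with adjusted p = 0.74 with an estimated correlation. The elongating list stood at 11.10, 11.18 and 11.18 in WT and 11.11, 11.07 and 11.05 in KO, and differed by -0.03 within WT 1, KO 2 and KO 3 and by -0.07 within the others; the round list differed by -0.03 and -0.09.

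With a term for those arrays both spermatid lists lost their call (adjusted p = 0.096 and 0.081), as did with the median of probe sets the round (0.18) and glucocorticoid (0.75, difference 0.0068) lists, with no moderation the glucocorticoid (0.092) and myoid (0.12) lists, and with array weights the myoid list (0.051). The round list also lost it without WT 2 (0.19) or KO 3 (0.17), the elongating list without KO 3 (0.050), the glucocorticoid list without WT 1 (0.25) or KO 1 (0.078), and the myoid list without WT 1 (0.10), WT 3 (0.18) or KO 1 (0.44).

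The remaining 19 lists did not pass, and 0 of their members passed when adjusted over the list alone. With 1 array left out, 4 of them did pass camera with the preset correlation: ribosomal proteins without WT 3 (adjusted p = 0.021) or KO 2 (0.020), oxidative phosphorylation without WT 3 (0.032), spermatocyte markers without WT 1 (0.042) or KO 1 (0.049), and interferon-stimulated genes without KO 1 (0.011). In the list of the tubulin tyrosine ligase-like family, 11 were measured, and camera gave an adjusted p of 0.88, with a median of 0.0022 and a mean of -0.0022. Its family members ranged from -0.06 (Ttll9) to 0.09 (Ttll12); Tpgs1 (listed as Gtrgeo22), at -0.08, and Tpgs2, at 0.02, are subunits of a tubulin polyglutamylase complex outside that family. The carboxypeptidases that remove glutamate from tubulin (6 measured, median -0.02, adjusted p = 0.51) ranged from -0.15 to 0.03; the lowest, Folh1, is a cell-surface glutamate carboxypeptidase outside the tubulin-modifying group, and Agtpbp1 stood at -0.03. Tubulins (13, median -0.02, adjusted p = 0.71), axonemal dyneins with radial spokes and central pair (33, median -0.02, adjusted p = 0.51), and intraflagellar transport and manchette genes (42, median -0.04, adjusted p = 0.26) did not pass. The most shifted member of the tubulins was Tubd1 at -0.21.

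Earlier germ cells and somatic cells gave small values as well. Spermatogonial markers had a median of -0.01 and a mean of 0.0017 (20 measured, adjusted p = 0.82, higher by camera) and meiotic spermatocyte markers of -0.06 (27, adjusted p = 0.11), with Sycp3, of the synaptonemal complex, at -0.16. Sertoli cell markers had a median of 0.02 (29, adjusted p = 0.51) with Trf, transferrin, at 0.35, androgen-responsive Sertoli genes 0.02 (17, adjusted p = 0.51), and endothelial markers 0.04 (17, adjusted p = 0.51). Markers of tissues that can be taken along with the testis, the epididymal epithelium (27, median 0.02, adjusted p = 0.51) and fat (12, median -0.05, adjusted p = 0.51), did not pass, with Gpx5 of the epididymis at 0.23.

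Steroid receptors and coregulators, the group of the partners ascribed to Ttll5, had a median of 0.02 and a mean of -0.01 over 18 genes (adjusted p = 0.87, higher by camera), from -0.22 (Nrip1) to 0.12. Interferon-stimulated genes (29, median 0.04, adjusted p = 0.11), apoptosis and p53 targets (27, median 0.012, mean -0.00032, adjusted p = 0.82, higher by camera), and heat shock and unfolded protein response genes (25, median -0.02, adjusted p = 0.89) did not pass. Neither did oxidative phosphorylation (41, median -0.04, adjusted p = 0.22), sperm glycolysis (18, median -0.02, adjusted p = 0.51; Pdha2 at -0.29) or cytosolic ribosomal proteins (22, median -0.09, adjusted p = 0.18).

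**Figure D4:**
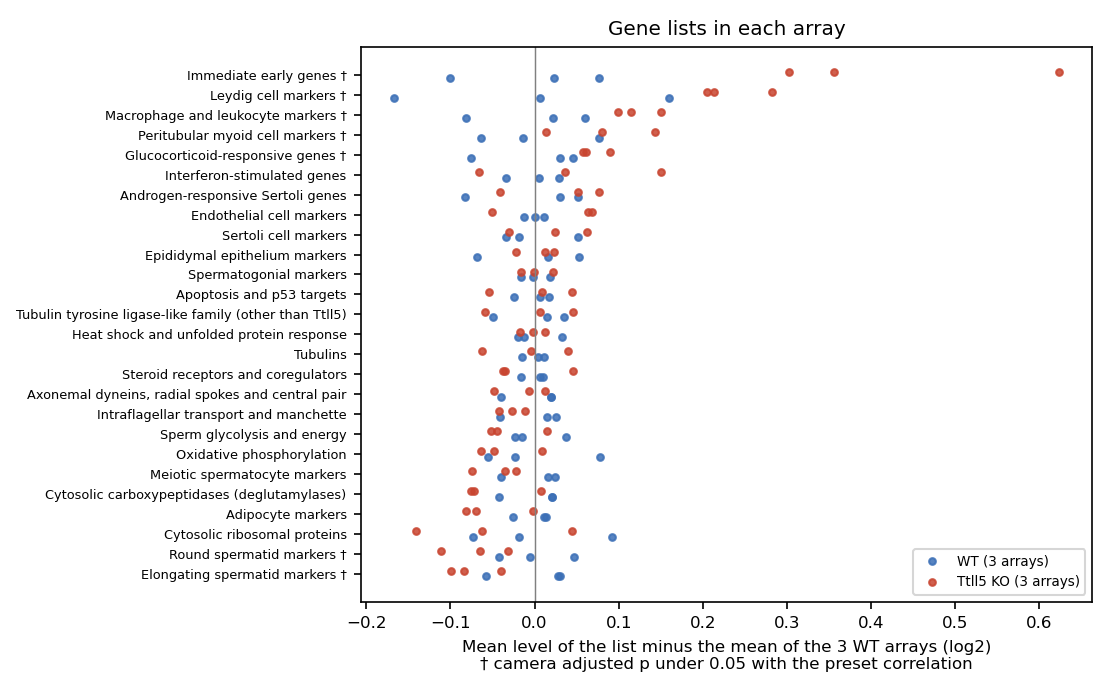
Mean level of each of the 26 gene lists in each array minus the mean of the 3 WT arrays (x axis, log2), 1 point per array, with lists on the y axis and a dagger on the 7 that passed camera with the preset correlation. The 3 KO arrays lie above all WT arrays for the immediate early, the Leydig cell, the macrophage and leukocyte, and the glucocorticoid-responsive lists.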

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

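Alternatives for genes of chromosomes 12 and 9, the variance per probe set, the term for 3 arrays (WT 1, KO 2, KO 3) with a higher lower quartile and the added lists were chosen after seeing the data; the others were planned. The Ttll5 level was past the threshold in all 16 alternatives, at -1.36 to -1.64. No called result reversed, and no setting moved the median of all genes by over 0.1. Where a value moved, the cause was not tested.

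Called genes numbered 11 (7 higher, 4 lower). With the median of probe sets there were 5 (4 higher, 1 lower), with trended and robust moderation 20 (12 and 8), without moderation 2 (1 and 1), with genes of 4 or more probe sets 19, and without chromosomes 12 and 9 there were 0 (820 at an unadjusted p under 0.05). The 0 was nearly fixed in advance, since all 11 calls of the main test lay on those chromosomes. Leaving out dim probe sets gave 11 higher. With 1 array left out there were 8 to 12 genes, 5 to 8 higher and 3 to 5 lower. Genes of other chromosomes were called in 10 of these settings: 3 of 12 without WT 1, 3 of 12 without WT 2, 3 of 12 without KO 1, 2 of 11 without KO 3, 2 of 20 with trended and robust moderation, 2 of 14 with dim genes left out, 1 of 15 with dim probe sets left out, 1 of 12 with quantile normalization again, 1 of 9 with the replicate block and 1 of 19 with genes of 4 or more probe sets. Probe sets numbered 72, and 125 with trended and robust moderation, 3 without moderation, 25 with the term for 3 arrays and 13 to 37 with 1 array left out. Exon use calls numbered 294, and 179 without dim probe sets, 183 with genes of 5 or more probe sets besides, 92 by F-test, 158 without chromosomes 12 and 9, 12 with a variance per probe set and 190 to 423 with 1 array left out. By Fisher's exact test, genes called near Ttll5 numbered 2, and 0 without moderation (p = 1), 0 within 5 Mb (p = 1) and 1 to 3 with 1 array left out. The 7 called lists became 0 with an estimated correlation and 0 with fry, and 5 to 8 with 1 array left out. Among named genes, Pik3r4 fell short of the threshold in 11 of 16 alternatives and Tdgf1 in 7 of 15. For exon use, moderation was robust without a trend, and lists without moderation used ranked statistics.

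The replicate numbers shared by the groups did not pair the arrays: deviations of arrays with the same number correlated at -0.17, 0.072 and 0.18, and WT 2 correlated better with KO 1 (0.22) than with KO 2. With the replicate block, 9 genes were called, 8 of them among the 11, as were 7 probe sets, 258 genes for exon use, 7 lists and 1 gene near Ttll5 (Fisher's exact p = 0.059). The weak signal of dim probe sets limits what can be measured in Tshr, Tdgf1, Scn10a and Serpina3g in WT.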

Other observations

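The explanations and tests of this part were chosen after the results were seen, while the counts and list results repeated from the report were planned, except those with a variance per probe set or a term for 3 arrays. Genes of cholesterol synthesis, a list written after the data were seen, had higher values in KO in 13 of 17 members, with a median difference of 0.15. Msmo1 (listed as Sc4mol) differed by 0.52 (SE 0.10) and Tm7sf2 by 0.44 (SE 0.094), with all 3 KO arrays above all WT arrays and neither past the threshold over all genes. With 28 lists the group passed camera with the preset correlation (adjusted p = 4.5e-05) but not with an estimated one (adjusted p = 0.499), so a group change stays open. Kallikrein 1-related peptidases, several of which mark Leydig cells, did not pass (12 measured, adjusted p = 0.35), with Klk1 at -0.48 (SE 0.16) and Klk1b22 at 3.47, 3.99 and 4.43 in WT, below the lower quartiles, and 4.88, 4.72 and 6.52 in KO, KO 3 apart from the rest.

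Called probe sets of genes other than Ttll5 lay on chromosomes 12 and 9. A candidate explanation is that the groups differ in stretches of chromosome from different founder strains, around the targeted gene on chromosome 12 and by the parents on chromosome 9. In 316 bins of 50 neighbouring genes, with genes that had a called probe set left out, 7 of the 10 bins richest in probe sets with p under 0.01 lay on these chromosomes, which hold 29 of the bins (exact hypergeometric p = 2.6e-06, highest bin 7.88%, median 0.958%). That p-value treats the bins as independent, although neighbouring bins can share a stretch. The chromosomes were also picked from the called probe sets of the same arrays, so the p-value overstates the evidence. A bin of chromosome 1 held 3.81%, the highest share on another chromosome and above some of the 7. Base differences under the probes could mimic expression changes. Of 358 other probe sets of the same genes, 19.6% moved the same way at p under 0.05 (bootstrap interval 12.1% to 30.5%), against 4.48% in neighbouring genes. The 4.48% is the larger of the shares higher and lower, pooled over both chromosomes and not matched to a direction per gene, so it is a rough baseline. The values go against base differences confined to the called probe sets. They cannot exclude base differences under several probe sets of a gene, so these stay open as the whole cause. For the 16 genes with fewer than 50% of probe sets moved, such as Gtf2a1, the rest differed by a median of 0.0917 in size, which both a base difference and a change of exon use allow, so these cannot be told apart without probe sequences. The 16 genes of chromosome 12 span 366 of 483 consecutive genes, and the 12 of chromosome 9 span 166 of 940; linked sequence, passenger differences and effects of Ttll5 loss stay open for each gene.

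Immediate early genes had higher values in all 3 KO arrays than in any WT array. A lower share of germ cells would raise Sertoli, endothelial and myoid genes alike, but their lists differed by a mean of 0.04145 (SE 0.025) against 0.43 (SE 0.11). A larger share of interstitial cells stays open, since the Leydig list without shared genes and the macrophage list differed by a mean of 0.1692 (SE 0.037), with the spermatid lists lower by camera's preset correlation only; this is below the immediate early list, but their intervals of 2 SE overlap. Handling of the tissue before RNA extraction may raise immediate early genes without other stress genes: the heat shock list differed by -0.002176, which does not decide it, so handling, cell makeup of the interstitium and a response to the knockout cannot be told apart. Hybridization or dissection order is not given in the labels used here.

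In KO, most Ttll5 probe sets kept a signal, although 1 of the 31 outside the pair had a KO mean of 4.27, just above that of the second of the pair. WT tissue or RNA in the KO samples would leave the same share everywhere, yet the pair that fell furthest kept at most 1.295% against at least 29.2% for the others. Background or cross-hybridization stays open: 29 of the 31 KO means lie above the median of all probe sets, but levels of different probe sets depend on probe affinity. A transcript that lacks part of the gene and is present at a lower level is a further hypothesis, not tested since probe positions are not used here.

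The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The other 9 set 2 WT and 1 KO array against 1 WT and 2 KO, so they keep part of any KO difference. Such a difference can also widen the spread within their groups and lower their counts of genes and probe sets. The real split gave 11 genes (highest other split 3), 72 probe sets (3), 12 genes for exon use with a variance per probe set (3) and 2 genes near Ttll5 (0), each reached by 1 split, the real one. It gave 294 genes with the planned exon use test, where 2 splits reached as many and the highest other gave 1059. For gene lists, 2 splits reached the real 7, with 7 as the highest other. The immediate early list had an adjusted p of 3.5e-21 in the real split, the smallest of the 10 and reached by 1 split, and also passed in 6 of the 9 splits that mix KO and WT arrays (3.9e-06 to 0.012). The split with 1059 sets WT 1, KO 2 and KO 3 against the other arrays. It points to a structure of the samples as that test sees it, but the same split called 3 genes, 0 probe sets and 0 genes with a variance per probe set, so it may rest on the test's calibration. Those 3 arrays have lower quartiles of 4.66, 4.67 and 4.67 against at most 4.64 for WT 2, WT 3 and KO 1. With a term for it the planned exon use test called 253 genes, and the gene test called 10.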
